A study of Homo sapiens with 12 samples.

How the data were processed

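Polyadenylated RNA was sequenced from SK-OV-3 cells (spelled SKVO3 in the sample titles), an established human ovarian cancer line that the labels present as a model of high grade serous ovarian cancer. The cells carried an empty vector (shEmpty) or a short hairpin RNA vector against NR3C1 (shNR3C1), and were grown either attached to plastic (2D) or as spheroids in ultra-low-attachment plates (3D). Both were harvested on day 6. The 4 groups held 3 libraries each, 12 in all. Per the labels' protocols, the libraries were made with the Illumina Stranded mRNA Prep.

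The submitters' processing notes name FastQC, cutadapt (version 4), STAR (version 2.7.10b), featureCounts (version 2.0.3) and DESeq2, and the builds hg38 and GRCh38.p13. The gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited whole-number read counts for 61071 gene symbols, and a second table of normalized signal for 22561 genes. From the values, that second table held the genes with at least 11 counts over the 12 libraries. Each deposited normalized value was the deposited count divided by 1 factor per library, and 100% of values gave back the count within 0.05. These factors equalled median-of-ratios size factors computed here from the counts. The counts were used for every main result and the normalized values only for 1 alternative.

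Total counts per library, in the order of replicates 1 to 3, were 20085865, 44546106 and 17398838 for shEmpty in 2D and 25776516, 19861239 and 26525204 for shNR3C1 in 2D. In 3D they were 17544628, 13163568 and 22923475 for shEmpty and 17835712, 5398563 and 18460939 for the libraries labelled shNR3C1. Groups and replicate numbers came from the labels. Nothing states whether replicates were separate cultures, so p-values measure only the spread between these libraries. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 2.60 to 20.1 between pairs.

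Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group were kept (16272), libraries were scaled by TMM, and a quasi-likelihood model with 4 group means was fitted to all 12 libraries with robust dispersions, leaving 8 residual degrees of freedom. The common biological coefficient of variation was 0.108, with 0.106 in the 2D and 0.110 in the 3D libraries. There were 5 two-sided comparisons: shNR3C1 against shEmpty in 2D and in 3D, 3D against 2D for each vector, and the interaction of vector and growth setting. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the F statistic. Levels are CPM from edgeR after TMM scaling, as mean ± SD with n = 3. Where a group had 0 counts, the fold is a bound from the pooled counts of the other group against a floor of 3 counts over the group. With 1 to 3 counts, a ratio of pooled counts is given with an exact 95% interval. Floors and intervals cover counting error only.

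There were 34 gene lists, fixed before the data were examined, with 657 of their 733 symbols tested. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjusted p-values of lists are over the 34 lists. The list called immediate early genes below was fixed as genes of the immediate early handling response, with heat shock genes among them. An effect of handling at harvest on that list was not tested. Beside the members called over all genes, the number called when adjusted over the list alone is given. Genes were named by a rule also fixed before the data were examined. It took NR3C1, then the 8 genes with the largest log2 fold changes in each direction (5 for the interaction) among called genes with a mean of at least 5 CPM in the higher group, a characterised symbol and, except for the interaction, libraries of the compared groups that did not overlap. It added 9 tested focus genes in the vector comparisons (FKBP5, TSC22D3, PER1, KLF9, CDH1, VIM, ALDH1A1, ABCB1 and MKI67), and up to 4 members with the smallest p from each list described. CDKN1C, also a focus gene, did not pass the filter. Of the genes that this rule takes, 1 is not reported here. NR3C1 coordinates came from GENCODE release 29 on GRCh38.

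The test was checked on simulated counts for 16272 genes, drawn with the real library sizes and dispersions and the mean of each gene over all 12 libraries. In each of the groups with the hairpin label, 200 genes were changed. In the 2D comparison, 54% of genes changed 1.5-fold, 66% changed 2-fold and 98% changed 4-fold were recovered. In 3D these shares were 52%, 64% and 100%, and for the interaction 40%, 50% and 90%. Unchanged genes made up 4.70%, 7.64% and 5.84% of the calls, respectively. The real comparisons called far more genes (1413, 7845 and 3714), so these shares need not hold for them.

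Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 (1.42.0) Wald test, fits to the compared groups alone, the replicate number as a block, leaving out each library, limma on log2 of the deposited normalized values plus 1, a minimum absolute log2 fold change of 1, an estimated inter-gene correlation, and fry. Counts of list members without the shallowest library were added after the data had been seen. Reads of near-identical genes can be split by counting. Values for PSG genes, CKMT1B, the AKR1C genes, HLA-B, MT2A, mitochondrial genes and ribosomal protein genes are therefore uncertain.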

Results

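RNA was measured in 12 libraries of SK-OV-3 ovarian cancer cells carrying an empty vector or a hairpin against NR3C1, the gene of the glucocorticoid receptor, in 2D or as 3D spheroids, with 3 libraries per group. Libraries held 5398563 to 44546106 counts, the fewest in replicate 2 of the 3D libraries labelled shNR3C1. The first principal component of log2 CPM, with 59.2% of the variance, separated 3D from 2D. The second, with 18.9%, separated the vectors within each setting.

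**Figure D1:**
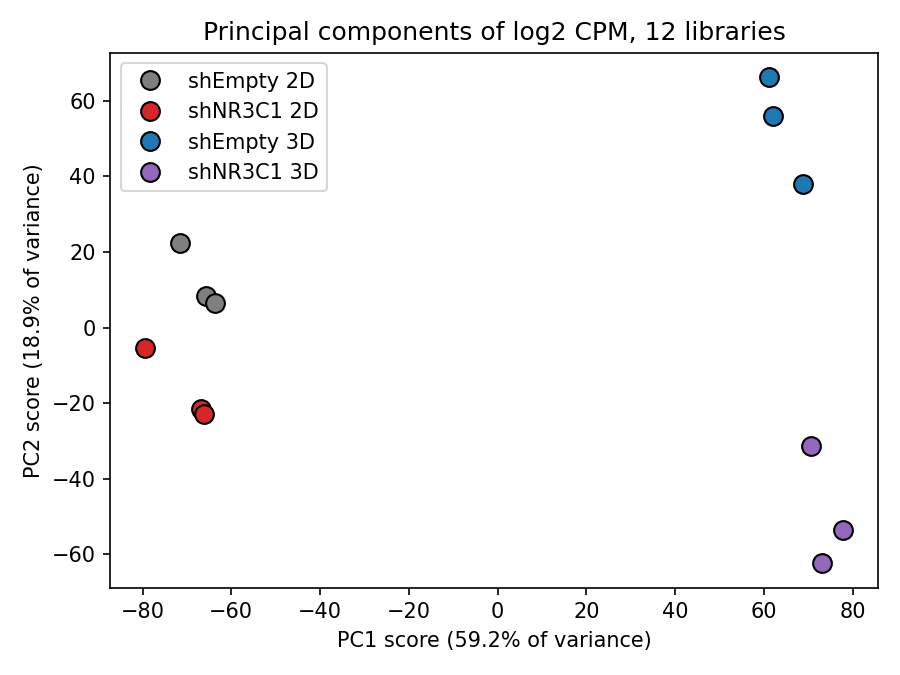
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by group as labelled. The components held 59.2% and 18.9% of the variance, and 2D libraries lie on the left and 3D libraries on the right.

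The targeted gene was examined first. NR3C1 (ENSG00000113580.14, a protein-coding gene on the minus strand of chromosome 5, 143277931 to 143435512, GRCh38) stood at 95.1 ± 9.5 CPM (SD, n = 3) in 2D cells with the empty vector and at 49.99 ± 0.12 CPM in 2D cells with the hairpin. The log2 fold change was -0.93 ± 0.10 (SE), with an adjusted p of 8.3e-07 by edgeR's quasi-likelihood test. In 3D, the level was 74.5 ± 9.7 CPM with the empty vector and 86.6 ± 9.8 CPM in the libraries labelled shNR3C1. That log2 fold change was 0.22 ± 0.10 (adjusted p = 0.079), so a lower NR3C1 level was not seen in the 3D libraries labelled shNR3C1. NR3C1 passed the threshold as higher there with the replicate number as a block (0.22, adjusted p = 0.046) and without replicate 3 of shEmpty in 3D (0.30, adjusted p = 0.040). The value fell to 0.12 without replicate 1 of the 3D libraries labelled shNR3C1 (adjusted p = 0.39) or replicate 2 of shEmpty in 3D (adjusted p = 0.38). From 2D to 3D, NR3C1 fell with the empty vector (log2 fold change -0.35, adjusted p = 0.0055) and was higher in the libraries labelled shNR3C1 (0.80, adjusted p = 5.8e-07). The vector effects differed between settings by 1.14 ± 0.14 on the log2 scale (adjusted p = 1.1e-05). Every 3D comparison that uses the libraries labelled shNR3C1 therefore carries a label that the transcript level of NR3C1 does not bear out. The fall from 2D to 3D with the empty vector lost its call without replicate 2 of shEmpty in 3D (log2 fold change -0.25, adjusted p = 0.054).

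**Figure D2:**
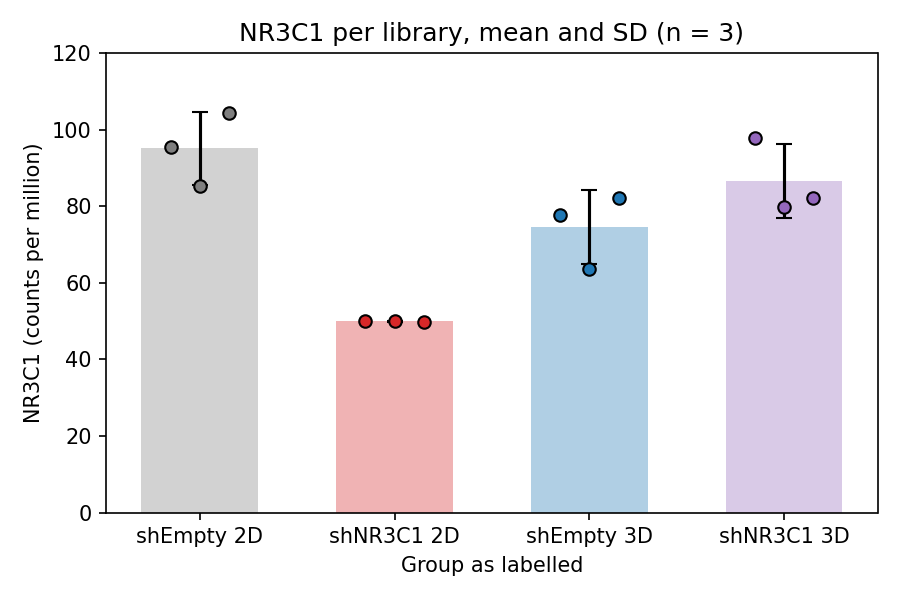
NR3C1 in CPM (y axis) for each group as labelled (x axis); bars are means, error bars SD (n = 3) and points single libraries. The 2D hairpin libraries have a mean of 49.99 CPM, and the 3D libraries labelled shNR3C1 have a mean of 86.6 CPM against 74.5 CPM with the empty vector.

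The first comparison set the hairpin against the empty vector in 2D. It cannot tell an effect of lower NR3C1 from another difference between the cells carrying each vector. Rose and fell here refer to the hairpin against the empty vector. Values with an error and no unit after gene names are log2 fold changes ± SE (n = 3 per group). Of 20 NF-kB and inflammatory genes tested, 12 rose and 0 fell (13 and 0 adjusted over the list alone). The list was called at an adjusted p of 1.1e-09 and kept its call at an adjusted p = 0.045 with an estimated correlation. The chemokine genes CXCL1 (40.7 ± 2.1 to 83.5 ± 4.7 CPM) and CXCL8 (6.93 ± 0.90 to 16.2 ± 2.1 CPM) and the NF-kB inhibitor gene TNFAIP3 (log2 fold change 0.93 ± 0.14) rose. ABCB1, which encodes the multidrug transporter P-glycoprotein, rose from 0.849 ± 0.288 to 7.31 ± 1.26 CPM (log2 fold change 3.19 ± 0.33). The aldo-keto reductase genes AKR1B10, AKR1C1 and AKR1C2 fell, AKR1B10 going from 55.2 ± 2.7 to 11.8 ± 0.53 CPM. Collagen genes COL1A1 (-2.51 ± 0.12) and COL1A2 (-2.64 ± 0.15) and the fibronectin gene FN1 (-1.39 ± 0.10) fell as well.

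The other 9 lists called in this comparison had an adjusted p of at least 0.12 with an estimated correlation. In the drug transport and detoxification list, 2 of 25 members rose and 9 fell (2 and 13 adjusted over the list alone; adjusted p = 4.7e-05, and adjusted p = 0.12 with an estimated correlation), including AKR1C1 (-0.84 ± 0.08) and AKR1C2 (-1.20 ± 0.09). Epithelial genes rose in 5 of 22 cases with 0 falling (6 and 0 adjusted over the list alone; adjusted p = 0.0010, and adjusted p = 0.45 with an estimated correlation), among them the keratin genes KRT8 (0.71 ± 0.08), KRT18 (0.79 ± 0.09) and KRT19 (1.24 ± 0.16). Of 14 immediate early genes 7 fell (7 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.28 with an estimated correlation), with EGR1 going from 231 ± 18 to 82.7 ± 8.5 CPM and FOS from 4.47 ± 0.39 to 2.72 ± 0.12 CPM. Hypoxia and glycolysis genes fell in 7 of 23 cases and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 3.9e-04, and adjusted p = 0.28 with an estimated correlation), as for ALDOC (-0.93 ± 0.17) and VEGFA (-0.34 ± 0.07). In the interferon list 5 of 21 fell (5 adjusted over the list alone; adjusted p = 0.010, and adjusted p = 0.50 with an estimated correlation). IFIT1 was at -0.88 ± 0.19. Smaller shifts were called for the lists of cholesterol synthesis (2 of 24 fell), lysosome (3 of 23 fell, CTSD at -0.74 ± 0.09), integrated stress response (3 rose and 2 fell of 20, TRIB3 at 0.74 ± 0.11) and YAP and TAZ targets (4 rose and 1 fell of 22, the latter CCN1 at -0.60 ± 0.08). Adjusted over the list alone, these counts were 2, 3, 4 and 2, and 6 and 1. With an estimated correlation their adjusted p-values were 0.45, 0.60, 0.45 and 0.60. Calls were lost without single libraries for cholesterol synthesis (replicate 3 of shEmpty, adjusted p = 0.087, or of shNR3C1, 0.062), lysosome (replicate 2 of shEmpty, 0.19, or replicate 1 of shNR3C1, 0.056), YAP and TAZ targets (replicate 2 of shEmpty, 0.14, or replicate 1, 0.11, or 2, 0.075, of shNR3C1) and, without replicate 3 of shEmpty, for the stress response and interferon lists (0.054 for both). Extracellular matrix genes fell in 9 of 25 cases and rose in 1 (11 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.052). The mesenchymal list was not called either (adjusted p = 0.55), with MMP2 at -2.45 ± 0.16.

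The genes with the largest increases in 2D after ABCB1 were the protocadherin gene PCDH19 (2.45 ± 0.17), the histone deacetylase gene HDAC9 (2.32 ± 0.23), S1PR1 (2.29 ± 0.14), MYH15 (2.24 ± 0.28), ALDH1A3 (1.83 ± 0.30), the vitamin D hydroxylase gene CYP24A1 (1.83 ± 0.16) and TMEM178B (1.81 ± 0.18). The largest decreases besides COL1A2 were in EGR3 (-3.69 ± 0.38), SAMD11 (-2.98 ± 0.16), ESPN (-2.91 ± 0.17), the calcium channel gene CACNA1H (-2.69 ± 0.18), the chemokine receptor gene ACKR3 (-2.66 ± 0.27), TOX (-2.54 ± 0.25) and the potassium channel gene KCNH3 (-2.54 ± 0.18). Known glucocorticoid receptor targets were not called as a list (adjusted p = 0.33). Of 19 tested, MT2A (1.14 ± 0.22) and ZBTB16 (1.48 ± 0.41) rose and TSC22D3 fell (-0.42 ± 0.11, adjusted p = 0.021). FKBP5 (0.44 ± 0.29), PER1 (0.24 ± 0.16), KLF9 (-0.29 ± 0.14), CDH1 (0.79 ± 0.55), VIM (-0.14 ± 0.09) and MKI67 (-0.14 ± 0.10) did not pass the test. TSC22D3, MT2A and ZBTB16 lost their calls without replicate 2 of shEmpty (adjusted p = 0.16, 0.063 and 0.22), as did ALDH1A1 (0.086). Other single libraries ended calls too: replicate 1 of shEmpty (0.055) and replicates 1 (0.073) and 3 (0.068) of shNR3C1 for TSC22D3, replicate 3 of shEmpty (0.053) for MT2A, and replicates 1 (0.065) and 2 (0.12) of shNR3C1 for ZBTB16. ALDH1A1 fell but was low in both groups (0.828 ± 0.307 and 0.155 ± 0.204 CPM).

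In total 1413 of 16272 genes were called in 2D, 547 higher and 866 lower with the hairpin, and 355 of them changed at least 2-fold. The count fell to 926 without replicate 1 and to 865 without replicate 2 of shEmpty in 2D.

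The same vectors were then compared in 3D. In the libraries labelled shNR3C1, most tested genes of the epithelial, mitosis, replication, ribosomal protein and cholesterol synthesis lists were higher. Most of the interferon and mitochondrially encoded lists were lower, as were 12 of 23 lysosomal genes (10 without the shallowest library). These lists were called with the preset correlation, and 0 of 34 lists were called with an estimated correlation (lowest adjusted p = 0.23). NR3C1 itself was not lower in these libraries, so none of these directions can be read as following a receptor transcript that was lower at harvest. Levels before harvest were not measured. The E-cadherin gene CDH1 stood at 155 ± 34 CPM against 30.4 ± 14.8 CPM (log2 fold change 2.35 ± 0.52), and VIM, which encodes vimentin, at 1266 ± 186 against 2225 ± 171 CPM. FN1 went from 7066 ± 416 CPM with the empty vector to 1896 ± 28 CPM. The glucocorticoid receptor target FKBP5 was higher, at 255 ± 54 against 56.1 ± 18.5 CPM.

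Epithelial genes were higher in 16 of 22 cases and lower in 0 (16 and 1 adjusted over the list alone; adjusted p = 2.2e-05, and adjusted p = 0.27 with an estimated correlation), including ESRP2 (2.11 ± 0.23), KRT18 (1.10 ± 0.09) and EPCAM (0.87 ± 0.10). Mesenchymal genes were lower in 10 and higher in 4 of 19 cases, without a call for the list (adjusted p = 0.11). ZEB1 (-1.26 ± 0.12), PRRX1 (-3.49 ± 0.34) and MMP2 (-2.95 ± 0.13) were among the mesenchymal genes that were lower. Extracellular matrix genes were higher in 8 and lower in 12 of 25, with a median log2 fold change of -0.31, a mean of 0.12 and no call (adjusted p = 0.35). Mitosis genes were higher in 18 of 22 cases and lower in 0 (18 and 0 adjusted over the list alone; adjusted p = 4.4e-08, and adjusted p = 0.27 with an estimated correlation), with AURKB at 1.31 ± 0.12, BUB1 at 1.23 ± 0.11 and MKI67 at 0.31 ± 0.10 (adjusted p = 0.052 for MKI67 without replicate 1 of the libraries labelled shNR3C1). DNA replication genes were higher in 18 of 24 (20 adjusted over the list alone; adjusted p = 9.8e-08, and adjusted p = 0.27 with an estimated correlation). RRM2 was at 0.98 ± 0.09. Homologous recombination and crosslink repair genes were higher in 14 and lower in 2 of 21 (14 and 2 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.33 with an estimated correlation). FANCA was at 0.73 ± 0.09. Of 26 ribosomal protein genes 23 were higher (25 adjusted over the list alone; adjusted p = 9.3e-08, and adjusted p = 0.34 with an estimated correlation). RPL14 was at 1.01 ± 0.09. All 13 mitochondrially encoded genes were lower (13 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.27 with an estimated correlation). MT-ND4 was at -0.63 ± 0.07. Mitochondrially encoded genes took 7.51 ± 0.26% of counts in 3D with the empty vector, 5.06 ± 0.46% in the 3D libraries labelled shNR3C1, and 4.88 ± 0.22% and 4.97 ± 0.18% in 2D with the empty vector and the hairpin.

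Cholesterol synthesis genes were higher in 18 and lower in 2 of 24 cases (18 and 2 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.23 with an estimated correlation), as for SQLE (1.05 ± 0.09) and IDI1 (0.91 ± 0.09). YAP and TAZ targets were higher in 15 and lower in 1 of 22 (16 and 2 adjusted over the list alone; adjusted p = 1.6e-05, and adjusted p = 0.27 with an estimated correlation), with the tissue factor gene F3 at 1.59 ± 0.14. Drug transport and detoxification genes were lower in 15 and higher in 3 of 25 (16 and 3 adjusted over the list alone; adjusted p = 1.7e-04, and adjusted p = 0.23 with an estimated correlation). AKR1C1 was at -1.44 ± 0.08 and AKR1C2 at -2.01 ± 0.09. ABCB1 was close to 0 in both 3D groups (0.0771 ± 0.0740 and 0.263 ± 0.131 CPM, adjusted p = 0.11). Interferon genes were lower in 13 and higher in 2 of 21 (14 and 2 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.31 with an estimated correlation). OAS2 was at -1.66 ± 0.21. Lysosomal genes were lower in 12 and higher in 1 of 23 (12 and 1 adjusted over the list alone; adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation). CTSA was at -0.66 ± 0.08. Integrated stress response genes were higher in 8 and lower in 3 of 20 (8 and 3 adjusted over the list alone; adjusted p = 0.027, and adjusted p = 0.31 with an estimated correlation). PHGDH was at 2.20 ± 0.24.

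Glucocorticoid receptor targets were higher in 10 and lower in 4 of 19 cases (10 and 4 adjusted over the list alone; adjusted p = 0.032, and adjusted p = 0.34 with an estimated correlation). PER1 (1.37 ± 0.15), ZBTB16 (2.79 ± 0.32) and DUSP1 (1.19 ± 0.11) were higher, PDK4 (-1.58 ± 0.18) and KLF9 (-0.50 ± 0.14) were lower, and TSC22D3 (-0.20 ± 0.11) did not pass. The list lost its call without replicate 2 of the 3D libraries labelled shNR3C1 (adjusted p = 0.064) or without replicate 3 of shEmpty in 3D (adjusted p = 0.058). The genes with the largest differences upward were HOXC6 (3.37 ± 0.58), TMEM156 (3.20 ± 0.52), GOLGA7B (3.20 ± 0.45), A2ML1 (2.97 ± 0.57), MCF2 (2.93 ± 0.52), CKMT1B (2.93 ± 0.65), SBSN (2.88 ± 0.34) and MDFI (2.83 ± 0.65). Downward they were the matrix gene POSTN (-5.24 ± 0.59), HMCN1 (-4.50 ± 0.28), the stem cell receptor gene LGR6 (-3.73 ± 0.28), SPARCL1 (-3.73 ± 0.34), SBSPON (-3.56 ± 0.23), the collagenase gene MMP13 (-3.54 ± 0.50), PRRX1 and CPXM1 (-3.41 ± 0.32). ALDH1A1 was also lower (-3.39 ± 0.41).

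In total 7845 genes were called in 3D, 3854 higher and 3991 lower in the libraries labelled shNR3C1, and 2193 changed at least 2-fold. Without the shallowest library, replicate 2 of that group, 7615 genes were called, 7212 of them shared with the full set in the same direction. In that fit the members higher went from 18 to 20 for mitosis and for replication and from 2 to 1 for interferon. The members lower went from 12 to 10 for lysosome, 13 to 12 for mitochondrially encoded, 15 to 14 for drug transport, 13 to 15 for interferon and 0 to 1 for epithelial genes. Among the 13 lists called, the other 6 had the same counts.

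The vector effects in 2D and 3D, which share no library, were compared across genes, which are not independent replicates. Pearson's r of the log2 fold changes was 0.40 and Spearman's rho 0.39 over 16272 genes. Pearson's r fell to 0.079 without a filter and 0.10 with DESeq2, both of which add genes with few counts. Of the genes called in 2D, 279 were higher in both settings and 586 lower in both, where independent lists would share 130 and 212. The directions were opposite for 70 and 59 genes, where independent lists would share 134 and 205.

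**Figure D3:**
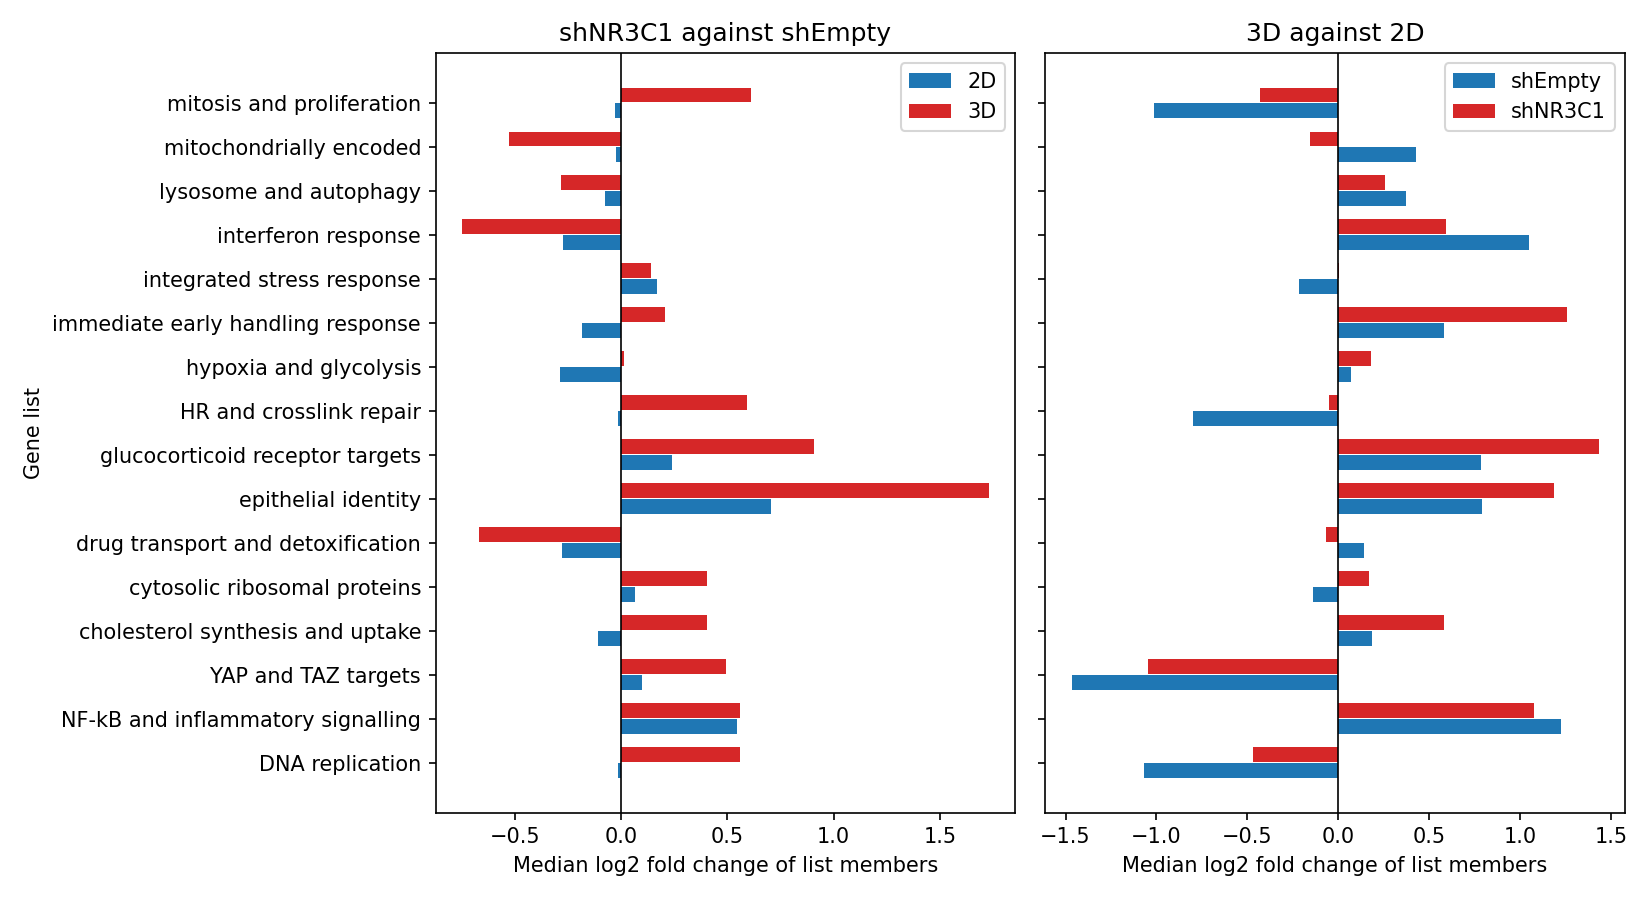
Median log2 fold change (x axes) of the tested members of each gene list called in either vector comparison (y axis), for shNR3C1 against shEmpty as labelled (left; blue 2D, red 3D) and for 3D against 2D (right; blue shEmpty, red shNR3C1). The median of the mitosis list was 0.61 in the 3D vector comparison and -1.01 for 3D against 2D with the empty vector.

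Growth as spheroids was compared with growth in 2D for the empty vector. Cell cycle genes and YAP and TAZ targets mostly fell, and more inflammatory, interferon and lysosomal genes rose than fell. These lists were called with the preset correlation, and 0 of 34 lists were called with an estimated correlation (lowest adjusted p = 0.17). The matricellular genes CCN1 (924 ± 76 to 37.5 ± 1.5 CPM) and CCN2 (959 ± 58 to 14.5 ± 2.0 CPM) fell strongly. So did the cytoskeletal genes TAGLN (543 ± 60 to 13.8 ± 1.8 CPM) and KRT80 (457 ± 15 to 6.67 ± 0.94 CPM). The superoxide dismutase gene SOD2 rose from 141 ± 3 to 486 ± 25 CPM, and MMP2 from 13.7 ± 2.1 to 204 ± 17 CPM.

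All 24 DNA replication genes fell (24 adjusted over the list alone; adjusted p = 2.6e-13, and adjusted p = 0.17 with an estimated correlation), with TYMS at -1.66 ± 0.07, and 21 of 22 mitosis genes fell (21 adjusted over the list alone; adjusted p = 1.4e-10, and adjusted p = 0.22 with an estimated correlation). CDC20 was at -1.69 ± 0.08 and FOXM1 at -1.62 ± 0.09. Repair genes fell in 13 and rose in 2 of 21 cases (13 and 2 adjusted over the list alone; adjusted p = 7.0e-04, and adjusted p = 0.32 with an estimated correlation). YAP and TAZ targets fell in 20 and rose in 1 of 22 (20 and 1 adjusted over the list alone; adjusted p = 1.9e-10, and adjusted p = 0.17 with an estimated correlation). NF-kB genes rose in 15 and fell in 2 of 20 (15 and 2 adjusted over the list alone; adjusted p = 3.3e-04, and adjusted p = 0.20 with an estimated correlation). ICAM1 was at 3.95 ± 0.36. Interferon genes rose in 15 and fell in 3 of 21 (17 and 3 adjusted over the list alone; adjusted p = 9.0e-04, and adjusted p = 0.28 with an estimated correlation). IFITM1 was at 5.08 ± 0.29 and IFI44L at 6.54 ± 0.50. Lysosomal genes rose in 13 of 23 (13 adjusted over the list alone; adjusted p = 9.2e-04, and adjusted p = 0.28 with an estimated correlation). CTSD was at 1.96 ± 0.10. Mitochondrially encoded genes rose in 12 of 13 (12 adjusted over the list alone; adjusted p = 9.0e-04, and adjusted p = 0.32 with an estimated correlation). MT-CYB was at 0.81 ± 0.08. The lists of immediate early genes (8 rose and 1 fell of 14, FOS at 3.57 ± 0.13), ERK feedback (14 rose and 5 fell of 23, SPRY4 at 2.63 ± 0.11), endoplasmic reticulum chaperones (10 of 18 rose, HSP90B1 at 0.70 ± 0.07) and MHC class I (7 rose and 1 fell of 17, HLA-B at 2.01 ± 0.10) were also called. These counts were the same adjusted over the list alone, MHC class I lost its call without replicate 1 of shEmpty in 2D (adjusted p = 0.052), and with an estimated correlation the adjusted p-values were 0.28, 0.25, 0.25 and 0.44. Glucocorticoid receptor targets were not called as a list (adjusted p = 0.059), although TSC22D3 (1.21 ± 0.11) and PDK4 (3.22 ± 0.19) rose.

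Several genes with 0 counts in 2D were present in 3D with the empty vector. MUC5B, which encodes a secreted mucin, reached 31.9 ± 4.6 CPM, at least 851-fold higher by pooled counts over the floor, and ITIH2 was at least 349-fold, MEFV at least 286-fold, CPXM1 at least 243-fold, IL33 at least 224-fold, LUM at least 181-fold, SELENBP1 at least 170-fold and GJA5 at least 161-fold higher. The endothelial marker gene PECAM1 rose from 0.0499 ± 0.0514 to 27.7 ± 3.5 CPM. EDN2 was at least 380-fold and PSG3 at least 93.2-fold lower in 3D. The pregnancy-specific glycoprotein genes PSG1 and PSG5 and the gene ANKRD1 kept 2 counts each in 3D, which gives ratios of 976 (95% interval 270 to 8067), 528 (146 to 4367) and 358 (98.9 to 2963) in favour of 2D. PSG4 (-7.01 ± 0.21) and SHISA9 (-6.10 ± 0.24) fell too. In total 8486 genes were called, 4442 higher and 4044 lower in 3D.

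The same contrast was made between the libraries labelled shNR3C1, where NR3C1 was higher in 3D than in 2D. YAP and TAZ targets were lower in 18 and higher in 2 of 22 cases (19 and 2 adjusted over the list alone; adjusted p = 9.0e-07, and adjusted p = 0.13 with an estimated correlation). CCN2 was at -5.61 ± 0.11, CCN1 at -3.50 ± 0.09 and ANKRD1 at -7.17 ± 0.34. DNA replication genes were lower in 19 of 24 (20 adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.20 with an estimated correlation), and mitosis genes lower in 14 and higher in 4 of 22 (15 and 4 adjusted over the list alone; adjusted p = 0.0068, and adjusted p = 0.49 with an estimated correlation). CDC20 was at -1.17 ± 0.08. Cholesterol synthesis genes were higher in 19 and lower in 2 of 24 (19 and 2 adjusted over the list alone; adjusted p = 2.0e-04, and adjusted p = 0.13 with an estimated correlation). SQLE was at 1.40 ± 0.09. Glucocorticoid receptor targets were higher in 13 and lower in 1 of 19 (13 and 1 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.20 with an estimated correlation). PER1 was at 1.92 ± 0.15, TSC22D3 at 1.43 ± 0.12 and ZBTB16 at 3.09 ± 0.32. Epithelial genes were higher in 15 and lower in 3 of 22 (15 and 3 adjusted over the list alone; adjusted p = 0.0098, and adjusted p = 0.44 with an estimated correlation). EPCAM was at 1.36 ± 0.10 and MUC1 at 1.65 ± 0.14. Immediate early genes were higher in 11 and lower in 1 of 14 (11 and 1 adjusted over the list alone; adjusted p = 1.5e-04, and adjusted p = 0.13 with an estimated correlation). FOS was at 4.53 ± 0.14. Apoptosis regulators were higher in 15 and lower in 5 of 23 (15 and 5 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.15 with an estimated correlation). They included the pro-apoptotic gene BMF (3.26 ± 0.15) among the higher and the anti-apoptotic gene BCL2L1 (-1.84 ± 0.07) among the lower. Of 8 stromal, endothelial and immune marker genes tested, 6 were higher and 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.028, and adjusted p = 0.15 with an estimated correlation). PECAM1 was at 14.7 ± 0.88 CPM against 0.0952 ± 0.1041 CPM. That list lost its call without replicate 2 of the 3D libraries (adjusted p = 0.063). Most of its markers did not pass the filter on low counts. A marker near 0 in 2D passes only through its level in 3D, so the direction is partly set by the filter.

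Further lists called in this contrast were ERK feedback (16 higher and 4 lower of 23), endoplasmic reticulum chaperones (15 of 18 higher), NF-kB (15 higher and 3 lower of 20), lysosome (12 of 23 higher) and interferon (9 higher and 3 lower of 21). Adjusted over the list alone these counts were the same except for NF-kB, with 15 and 4. With an estimated correlation their adjusted p-values were 0.13, 0.13, 0.20, 0.44 and 0.48. The interferon list lost its call without replicate 3 in 2D (adjusted p = 0.058) or replicate 2 (0.058) or 3 (0.062) in 3D.

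Except for PPP1R1A, the genes named for the largest differences upward had 0 counts in 2D with the hairpin. MUC5B was at least 407-fold, LAPTM5 at least 348-fold, CD52 at least 268-fold, ADCYAP1R1 at least 224-fold, ITIH2 at least 208-fold, ST8SIA4 at least 169-fold and AGR2 at least 154-fold higher in 3D, and PPP1R1A rose from 0.0945 ± 0.1043 to 49.2 ± 9.6 CPM. PSG1 was at least 815-fold and EDN2 at least 255-fold lower. SHISA9, PSG5, PSG3 and TRPC4 kept 2 counts each, with ratios of 353 (95% interval 97.5 to 2918), 342 (94.4 to 2827), 251 (69.4 to 2079) and 182 (50.1 to 1503). CYP24A1 fell from 47.8 ± 2.0 to 0.225 ± 0.196 CPM and ABCB1 from 7.31 ± 1.26 to 0.263 ± 0.131 CPM. In total 9086 genes were called, 4889 higher and 4197 lower, and 8728 without the shallowest library. The 3D effects with the 2 vectors correlated across genes with a Pearson's r of 0.81 and a Spearman's rho of 0.70. Without a filter this r was 0.38, and with DESeq2 it was 0.45. With both vectors 3001 genes were higher in 3D and 2717 lower, where independent lists would share 1335 and 1043.

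The interaction tested whether the vector effect differed between settings, with NR3C1 in 3D going against the label. Higher and lower refer to the signed log2 fold change. A fall that was weaker in 3D therefore also counts as higher, and a weaker rise as lower. Mitosis genes had a higher vector effect in 3D in 17 of 22 cases and a lower one in 0 (20 and 0 adjusted over the list alone; adjusted p = 5.2e-10, and adjusted p = 0.19 with an estimated correlation). BUB1 was at 1.29 ± 0.15. The same held for 19 of 24 replication genes (20 adjusted over the list alone; adjusted p = 1.5e-09, and adjusted p = 0.19 with an estimated correlation), with RRM2 at 0.998 ± 0.123, and for 17 of 24 cholesterol synthesis genes (19 adjusted over the list alone; adjusted p = 1.8e-09, and adjusted p = 0.059 with an estimated correlation). SQLE was at 1.05 ± 0.12. Ribosomal protein genes were higher in 14 of 26 cases (16 adjusted over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.38 with an estimated correlation), with RPL14 at 0.85 ± 0.13, and mitochondrially encoded genes lower in 10 of 13 (12 adjusted over the list alone; adjusted p = 1.1e-06, and adjusted p = 0.23 with an estimated correlation). MT-ND4 was at -0.64 ± 0.10. Immediate early genes were higher in 8 and lower in 1 of 14 (10 and 1 adjusted over the list alone; adjusted p = 7.6e-05, and adjusted p = 0.19 with an estimated correlation). EGR1 was at 1.47 ± 0.15 and EGR3 at 3.12 ± 0.44. The lists of YAP and TAZ targets (9 higher and 0 lower of 22), repair (10 and 1 of 21), epithelial genes (6 and 2 of 22), drug transport (2 and 9 of 25), ERK feedback (9 and 1 of 23), hypoxia (11 and 3 of 23), interferon (1 and 3 of 21), integrins (8 and 5 of 24), oxidative phosphorylation (4 and 0 of 26) and glucocorticoid receptor targets (6 and 3 of 19) were called as well. Adjusted over the list alone, the counts were 9 and 0, 11 and 1, 7 and 2, 2 and 11, 9 and 1, 11 and 3, 1 and 3, 9 and 5, 3 and 0, and 7 and 3. With an estimated correlation their adjusted p-values ranged from 0.19 (ERK feedback) to 0.50 (oxidative phosphorylation). Calls were lost without replicate 1 (0.052 to 0.062 for interferon, oxidative phosphorylation and receptor targets), 2 (0.054 for hypoxia and 0.099 for oxidative phosphorylation) or 3 (0.052 for integrins) of shEmpty in 2D. They were also lost without replicate 2 (0.059 for oxidative phosphorylation) or 3 (0.054 for integrins and 0.052 for receptor targets) of shNR3C1 in 2D. In 3D, this held without replicate 3 of shEmpty (0.079 for oxidative phosphorylation and 0.083 for receptor targets). It also held without replicate 1 (0.071 for interferon, 0.075 for oxidative phosphorylation and 0.058 for receptor targets) or 2 (0.079 for receptor targets) of the libraries labelled shNR3C1. Single genes with a lower vector effect in 3D included CXCL8 (-1.04 ± 0.19), HMOX1 (-1.42 ± 0.18), KRT8 (-0.76 ± 0.12), KRT19 (-1.62 ± 0.23), VIM (-0.68 ± 0.13) and ZEB1 (-1.04 ± 0.17), and those with a higher one included CCN1 (1.12 ± 0.12), DUSP1 (0.85 ± 0.15) and COL1A1 (1.92 ± 0.17).

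Of the genes named by size in the interaction, KRT5, which encodes a basal keratin, was at 2213 ± 485 CPM in the 3D libraries labelled shNR3C1 and at 408 ± 207, 354 ± 122 and 483 ± 44 CPM in 3D with the empty vector, 2D with the hairpin and 2D with the empty vector (interaction 2.89 ± 0.55). TMEM156 (3.82 ± 0.81), SCARA3 (3.09 ± 0.40) and S1PR3 (3.03 ± 0.44) were also higher. SPARCL1 (-3.77 ± 0.55), MMP13 (-3.74 ± 1.03) and LGR6 (-3.56 ± 0.46) were lower. LUM and GJA5 had 0 counts in 2D with the empty vector, so no fold is given for them; in 3D, LUM stood at 6.75 ± 0.66 CPM with the empty vector. In total 3714 genes were called, 2075 with a higher and 1639 with a lower vector effect in 3D, and 3723 without the shallowest library. MMP13 (adjusted p = 0.11) and GJA5 (adjusted p = 0.070) lost their calls without replicate 1, and LUM (adjusted p = 0.052) without replicate 3, of shNR3C1 in 2D.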

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

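The tests of exchanged labels, a single wrong label, library scaling and a shared spread were chosen only after the result was seen.

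The vector effect differed between 2D and 3D, by the edgeR interaction test, for 3714 genes. This count was set against 60 relabelings drawn within each setting, the real one included. As many genes were called in 7 of the 60, the highest of the others giving 6974, so this count does not exclude chance. Of the other relabelings, 8 kept the 3D groups whole, and the 6 that reached the real count were all among these. Where 3D groups were mixed, the highest count was 34. Such counts point to a structure of the samples, the difference between the 3D groups. An interaction on mixed 2D groups also picks it up, so these relabelings cannot decide about chance. For each simple comparison, the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 1413 genes in 2D against a highest other of 2, and 7845 in 3D, 8486 for 3D against 2D with the empty vector and 9086 for the libraries labelled shNR3C1, each against a highest other of 0. In every case 1 split, the real one, gave as many.

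The vector effect on NR3C1 differed between settings by 1.14 on the log2 scale. NR3C1 was not lower in the 3D libraries labelled shNR3C1, and 3 technical explanations were weighed. If the labels of the 3D groups had been exchanged, genes changed at least 2-fold in 2D should mostly change the other way in 3D, but 87.0% of the 355 had the same sign. A single wrong label among the 3D libraries is argued against by the lowest log2 fold change over the 6 leave-outs, 0.12. Scaling by a factor per library leaves ranks as they are, and 68.4% of tested genes had a lower log2 fold change in 3D than NR3C1 (55.1% at its value minus 2 SE), against 3.69% in 2D. The shared signs show that the direction of the vector difference was largely kept in 3D for these 355 genes. They say nothing about its size. Of the 1413 genes called in 2D, 865 were also called in 3D in the same direction, and 507 had a called interaction. The shared signs cannot tell an effect of the hairpin from another lasting difference between the cells carrying each vector. A later loss of the hairpin and a recovery of the transcript stay open.

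More genes were called between the vectors in 3D than in 2D. With all libraries thinned to the total of the shallowest, 6811 and 938 genes were called, a ratio of 7.26, which argues against depth. With each comparison fitted on its own 6 libraries the ratio was 4.503, which argues against a shared spread. A biological difference between settings stays open and was not tested.

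By the interaction test, the vector effect differed between settings for 52 of the 80 genes reported in the vector comparisons. The share over all 16272 genes was 22.8%. Most of the genes reported were named for a large fold or a small p in a vector comparison, so a larger share follows in part from that choice. Signs below are those of the difference, so a fall that was weaker in 3D also counts as higher. The vector effect was higher in 3D, in log2 units, for TMEM156 (3.82), EGR3 (3.12), GOLGA7B (2.40), SBSN (2.36), COL1A1 (1.92), KCNH3 (1.84), SAMD11 (1.83), ESPN (1.83), FKBP5 (1.75), PHGDH (1.59), CACNA1H (1.52), EGR1 (1.47), BUB1 (1.29), ESRP2 (1.26), F3 (1.23), PER1 (1.13), CCN1 (1.12), SQLE (1.05), AURKB (0.998), RRM2 (0.998), FOS (0.96), IDI1 (0.91), RPL14 (0.85), DUSP1 (0.85), COL1A2 (0.83), ALDOC (0.69), FANCA (0.63), EPCAM (0.51), MKI67 (0.44) and VEGFA (0.35). It was lower for SPARCL1 (-3.77), MMP13 (-3.74), LGR6 (-3.56), PCDH19 (-2.96), HDAC9 (-2.61), PRRX1 (-2.52), CYP24A1 (-2.01), S1PR1 (-1.85), KRT19 (-1.62), PDK4 (-1.50), OAS2 (-1.06), ZEB1 (-1.04), CXCL8 (-1.04), AKR1C2 (-0.81), CXCL1 (-0.77), KRT8 (-0.76), VIM (-0.68), MT-ND4 (-0.64), AKR1C1 (-0.60), CTSA (-0.58) and FN1 (-0.51).

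Over all 34 lists, the vector effect differed between settings by camera for 16. Of 16 gene lists called in either vector comparison, a choice that favours such lists, this held for 13. Adjusted p-values were 5.2e-10 for mitosis, 1.5e-09 for DNA replication, 1.8e-09 for cholesterol synthesis, 1.1e-06 for mitochondrially encoded and for ribosomal protein genes, 7.6e-05 for immediate early genes, 6.7e-04 for YAP and TAZ targets, 6.9e-04 for repair, 0.0033 for epithelial genes, 0.0082 for drug transport and detoxification, 0.027 for hypoxia and for interferon, and 0.039 for glucocorticoid receptor targets. The lowest of these with an estimated correlation was an adjusted p of 0.059, for cholesterol synthesis.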

How the results depend on the processing

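The alternatives were fixed before the data were examined, except the list counts without the shallowest library. All 5 counts of called genes moved when a minimum absolute log2 fold change of 1 was added, to 355 and 2193 for the vectors in 2D and 3D, 3237 and 3668 for 3D against 2D with the empty vector and in the libraries labelled shNR3C1, and 947 for the interaction; a stricter threshold calls fewer genes by construction. Without single libraries, these counts ranged from 865 to 1362, 6283 to 7666, 7424 to 7975, 8235 to 8770 and 2797 to 4071. NR3C1 in 3D passed the threshold under the block (log2 fold change 0.22, adjusted p = 0.046) and without replicate 3 of shEmpty in 3D (adjusted p = 0.040), and its values without single libraries ranged from 0.12 to 0.30. For 3D against 2D with the empty vector it ranged from -0.43 to -0.25. The cause was not tested. Under an estimated correlation, 1 list was called in 2D and 0 in each other comparison by camera (fry called 11, 27, 25, 28 and 23). The fry count was over 1.5 times the main one for the vectors in 3D (27) and for 3D against 2D (25 and 28), and fry does not compare a list with other genes. The correlation of vector effects fell to 0.079 without a filter and 0.10 with DESeq2, both of which add genes with few counts, and was 0.51 over genes called in either comparison. Without single libraries it ranged from 0.29 to 0.43. The correlation of 3D effects was 0.38, 0.45 and 0.84 in the same order, 0.79 with limma on normalized values, and 0.76 to 0.82 without single libraries.

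Whether replicate numbers pair the libraries stayed unclear. Same-number residuals correlated between -0.097 and 0.20, and other pairs between -0.19 and 0.16. Of the same-number pairs, 4 of 18 were over 0.1, and 7 of 12 libraries correlated best with their own number. Among pairs of unlike number, which were more numerous, those over 0.1 were at 0.158, 0.109 and 0.101. Each library had fewer candidates of its own number than of other numbers. The replicate block gave 1656, 7994, 8668, 9208 and 4145 called genes, more than the main fit in each comparison. Over 185 single gene results and their alternatives, the side of the threshold was the same in 2327 cases, called or not, a call was lost in 17 and gained in 1. Without single libraries, TSC22D3, ALDH1A1, MT2A and ZBTB16 lost their calls in 2D (adjusted p up to 0.22), and MKI67 in 3D (adjusted p = 0.052). With limma, CYP24A1 (1.84, adjusted p = 0.096) and ACKR3 (-2.66, adjusted p = 0.15) lost theirs in 2D at similar folds, and ABCB1 gained one in 3D (1.37, adjusted p = 0.047). ZBTB16 also lost its 2D call with the compared groups fitted alone (adjusted p = 0.067). Called lists kept their call in 647 cases outside the estimated correlation and lost it in 34. The shallowest library, at 5398563 counts, limits what low genes show in 3D.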

Other observations

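The carry-over tests were chosen only after the result was seen, and the pattern itself was noticed in the data. KRT5, CDH1 and MDFI, which stood higher in the 3D libraries labelled shNR3C1, also had a wide spread in 3D with the empty vector. There CDH1 was at 30.4 ± 14.8 CPM, KRT5 at 408 ± 207 CPM and MDFI at 6.56 ± 4.68 CPM (SD, n = 3). For each of the other 9 libraries, the displacement from its group mean towards the mean of the 3D libraries labelled shNR3C1 was taken. It was the median over genes called and raised at least 2-fold in 3D. Their mean in those 3D libraries had to reach 5 CPM and exceed the mean of the library's own group more than 2-fold. The genes thus differed by group, with 540 for shEmpty 2D, 482 for shNR3C1 2D and 737 for shEmpty 3D. The displacement ranged from -8.43% to 12.3% of the distance, with replicate 1 of shEmpty in 3D at the top.

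A linear trend on GC content and gene length is argued against, since 98.3% of this range was left after its removal, with values for 96.4% of the raised genes. If a fraction of cells with another expression state varied in share, lowered genes should be displaced in the same libraries. The displacements of raised and lowered genes correlated with a Pearson's r of 0.90 (exact permutation within groups, two-sided p = 0.060) and a Spearman's rho of 0.88 (p = 0.056) over 9 libraries, and r was 0.72 without the 2 farthest. The p misses 0.05, so a varying cell fraction may be present but cannot be told apart from other shared variation.

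Carry-over of RNA or reads from the 3D libraries labelled shNR3C1 would add at least the carried share of its source level to each gene, so several genes bounded under the needed share exclude it as the whole cause. That share was taken as the range of displacement in a group: 6.41% in shEmpty 2D (95% bootstrap interval over genes 6.05 to 6.71%), 11.1% in shNR3C1 2D (10.6 to 11.5%) and 20.7% in shEmpty 3D (20.1 to 21.2%). The libraries with the highest displacement were examined over 10537 genes at 5 CPM or more in each source library. There, 6 genes in shEmpty 2D and 21 in shNR3C1 2D had an upper counting bound under the interval. The lowest bounds were 1.41% and 1.42%. These bounds argue against carry-over as the whole cause in both 2D groups. In shEmpty 2D this holds only with the margin chosen last, after a stricter margin had found too few genes. In shEmpty 3D there were 0 such genes in the library with the highest displacement and 55 in the library with the lowest, as carry-over needs. A varying cell fraction would give the same, so carry-over stays open there.

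That test replaced others whose results had been seen. A form on 30 genes at least 32-fold higher in 3D, with a median of 1.08%, was set aside because of its choice of genes. Forms that required 10 genes at 50 CPM or more found 2 below 2.22% in each 2D library, or 1, 3 and 0 below 0.5 of the needed share in the 3 groups. A form that required 3 genes at 5 CPM or more below 0.5 of the share found 2, 9 and 0, and its margin was replaced by the interval after that. No form that required 10 genes was met, and the form below 0.5 of the share was met only in shNR3C1 2D.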
